A study of Mus musculus with 6 samples.

How the data were processed

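Polyadenylated RNA from cultured macrophages was sequenced in 6 libraries, 3 from Ube3a knockout mice and 3 from wild-type littermates, and the genotype of each library was taken from its title. Per the labels' protocols, total RNA was purified on Direct-zol columns, quantified on a Qubit fluorometer and made into libraries with a KAPA mRNA HyperPrep kit. Per the submitters' processing notes, Trimmomatic 0.36, HISAT2 2.1.0, HTSeq 0.11.0, FastQC 0.11.15 and Cufflinks were used. The roles of these tools, the genome build, the annotation, the strand setting of the counting and the tool behind the deposited comparison are not given in the sources used here.

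The authors deposited a single table of 16836 genes, which holds 1 expression value per gene and library, a log2 fold change and a p-value. Per the file headers the expression values are CPM, and from their range (−3.94 to 14.4) they are log2 CPM with a prior count added to each gene. The deposited p-values are the authors' own, not adjusted for multiple testing, and were used only for comparison. The decimal mark of every value of size 1 or more had been lost when the table was saved, so those values could be read in more than one way. In each library, 2 to the power of the value, minus the shared offset of genes without a read, is a whole multiple of 1 fixed step, which is the CPM of 1 read. This fixed the decimal mark of each value that had 2 possible readings, and returned whole reads, within 1e-06 of a whole number, for 100% of the genes in each library. The step gives the library size on which the authors scaled, 0.982 to 1.02 times the reads in the table. On simulated values, 100% of reads were recovered by the same steps. Every gene in the table had at least 10 reads over the 6 libraries and a read in at least 3, and genes outside the table, among them the Y-linked genes looked for, were not analysed here. In the authors' deposited table, 725 of 16830 readable p-values were under 0.05. Over all genes, limma-voom on the recovered reads gave p-values that differed from the authors' deposited table by at most 5.32e-11 as a relative gap. A further 6 p-values and 8 fold changes in exponent form were not used.

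The design was fixed before the data were examined, as were the named-gene rule, the gene lists and most alternatives. It asked for a test on raw counts, with a second test for a table of normalized values. Since the deposited columns hold log2 CPM and not counts, the second test was used. CPM were computed from the recovered reads and the authors' scaled library sizes, genes with at least 1 CPM in at least 3 libraries were kept (12118 genes), and log2(CPM + 1) was fitted with limma 3.58.1 (eBayes with an intensity trend) in R 4.3.3, with genotype as the only term. The pseudocount of 1 shrinks the fold changes of genes near 1 CPM. A gene is called changed at a Benjamini-Hochberg adjusted p under 0.05, two-sided, and intervals are at the 95% level. edgeR and DESeq2, named in the plan for raw counts, were not used, although the recovered reads would have allowed them.

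Gene lists were tested with camera (limma) on the deposited log2 CPM of the same genes, with a preset correlation of 0.01, for pathway and cell-type lists with at least 5 tested genes, with Benjamini-Hochberg adjustment over the 32 lists. In all 41 lists were drawn up from textbook knowledge, with 571 of their 750 genes tested. Changed genes were also counted on the chromosome of Ube3a and within 10 Mb of it, and tested with Fisher's exact test. Positions come from GENCODE M21 on GRCm38, matched by Ensembl identifier for 16820 of the 16836 genes. The build the authors used is not known, and gene boundaries are those of GENCODE M21.

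Genes named in the text are Ube3a and the changed genes, up to 15 per direction by fold change, with an average log2 CPM of at least 1 and no overlap between genotypes, where predicted models and unnamed identifiers are only counted. Since fewer than 10 passed, the 5 with the smallest unadjusted p in each direction were added. So were up to 4 changed members of each list, or the 2 with the smallest p where none changed, and a set named in any case (among them Snrpn, Snhg14, Abca1, Abcg1, Il1b, Tnf, Mmp9, Xist and Ddx3y, where the table holds them). A member given only by its log2 fold change did not pass the threshold. A few named genes are not reported here, though they stayed in all tests and lists.

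Depth was 25454862 to 35517269 reads per library, so that 1 read was worth 0.0277 to 0.0400 CPM. The 10 most abundant genes took 6.88% to 8.41% of the reads in a library. Libraries of one genotype differed by far more than sampling noise, with a chi-square per degree of freedom of 10.9 to 44.1, so none were merged, which does not show that they came from separate animals or cultures. The limma step was tested on simulated reads for the 12118 genes, with 200 genes changed by 1.5-fold, 2-fold or 4-fold and a list of 25 genes shifted by 1.3-fold. It called 74.6% of genes changed by 1.5-fold, 95.5% by 2-fold and 97.0% by 4-fold, and 4.17% of its 192 calls, those of the shifted list included, were of unchanged genes. Benjamini-Hochberg adjustment asks for a smaller unadjusted p when fewer genes are called. The real data gave 2 calls, so these rates are too high for the real comparison. In the real data the median standard error of a log2 fold change was 0.0965, against 0.0917 in the simulation. For camera, the shifted list was called, and 0 of 50 unshifted lists were. The simulated genes varied independently of each other, so this could not test whether the preset correlation is large enough for real lists.

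The alternatives set down with the design were other size factors, other filters, the replicate number as a block, leaving out each library, Xist as a covariate, pseudocounts of 0.5 and 5, limma-voom, a limit on the fold change, camera with an estimated correlation, fry, and windows of 5 and 20 Mb. Tests on the deposited log2 CPM, limma-voom over the whole table, leaving out both libraries with almost no Xist, and unscaled library totals were added after the data were seen, as were 20 random thinnings of all libraries to the depth of the smallest. Figures were drawn with matplotlib 3.10.9.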

Results

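RNA sequencing measured polyadenylated transcripts in mouse bone marrow-derived macrophages, cells that are matured in culture from marrow precursors. Libraries came from Ube3a knockout mice (KO) and from their wild-type littermates (WT), with 3 libraries per genotype. Ube3a encodes an E3 ubiquitin ligase of the HECT family, which in neurons is expressed from the maternal chromosome. The table covered 16836 genes, and the reads assigned to them numbered 25454862, 30957583 and 32294791 in KO replicates 1 to 3, and 31046256, 28651459 and 35517269 in WT replicates 1 to 3. Levels are given as CPM, read counts brought to one shared library size, on the authors' scaled library sizes, as mean ± SD with n = 3 per genotype. Of these genes, 12118 reached 1 CPM in at least 3 libraries and were tested with limma on log2(CPM + 1), a scale that understates the change of low genes. The labels do not say that each library came from a separate animal, so p-values measure the spread between these samples, which may be technical in part. Xist had 28 reads in KO replicate 2 and 14 in WT replicate 2, against 30161 to 42232 in the other libraries. This argues against replicate 2 of either genotype being a repeat of the same cells as replicates 1 and 3, which may themselves share a source. The question of the comparison was how loss of Ube3a alters the macrophage transcriptome.

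The knockout libraries held Ube3a transcript well under the wild-type level. Ube3a (ENSMUSG00000025326, chromosome 7: 59228750 to 59311536, plus strand, GRCm38) stood at 69.3 ± 7.94 CPM in KO and 192.8 ± 14.8 CPM in WT, so that KO had 35.9% of the WT level. All 3 KO libraries, at 61.2 to 77.0 CPM, lay below all 3 WT libraries, at 177.6 to 207.1 CPM. The log2 fold change was −1.47 (95% interval −1.69 to −1.24), and Ube3a fell past the threshold (limma with Benjamini-Hochberg adjustment, adjusted p = 0.00444). A two-sided exact permutation test of the 3 against 3 CPM values gave p = 0.1, the smallest value that groups of this size allow. Gene-level reads do not show which exons the remaining transcript holds, and the knockout allele is not described in the labels. Between 1742 and 2499 reads per KO library lay on Ube3a.

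Apart from Ube3a, a single gene changed with genotype among the 12118 tested. Fah, which encodes fumarylacetoacetase, the last enzyme of tyrosine breakdown, rose to 13.2 ± 2.17 CPM in KO from 4.28 ± 0.646 CPM in WT. Its log2 fold change was 1.42 (95% interval 1.10 to 1.74), or 3.08 times the WT level in CPM (limma with Benjamini-Hochberg adjustment, adjusted p = 0.0481). Fah (ENSMUSG00000030630) lies at chromosome 7: 84585159 to 84606722 on the minus strand, 25.3 Mb from Ube3a. Both changed genes had all 3 KO values on one side of all 3 WT values, which was so for 9.95% of tested genes, against 10% by chance. An unadjusted p under 0.05 was reached by 500 genes, of which 204 were higher and 296 lower in KO, where 605.9 were to be expected by chance. On the log2(CPM + 1) scale the measurements bounded most genes, since the 95% interval lay within 1.5-fold of no change for 90.4% of the tested genes. Because this scale understates the change of low genes, larger changes in CPM remain possible for them. Ube3a passed the threshold in each of 19 alternative fits, but Fah passed in 10 of its 19. The Fah adjusted p was 0.116 without KO replicate 1, 0.164 without KO replicate 2, 0.407 without KO replicate 3, 0.371 without WT replicate 1 and 0.3595 without WT replicate 3, and with limma-voom on the same genes it was 0.0756. Its log2 fold change stayed between 1.298 and 1.517 with 1 library left out. With all libraries thinned to equal depth, Fah passed in 11 of 20 random thinnings (limma adjusted p from 0.0240 to 0.0918).

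**Figure D1:**
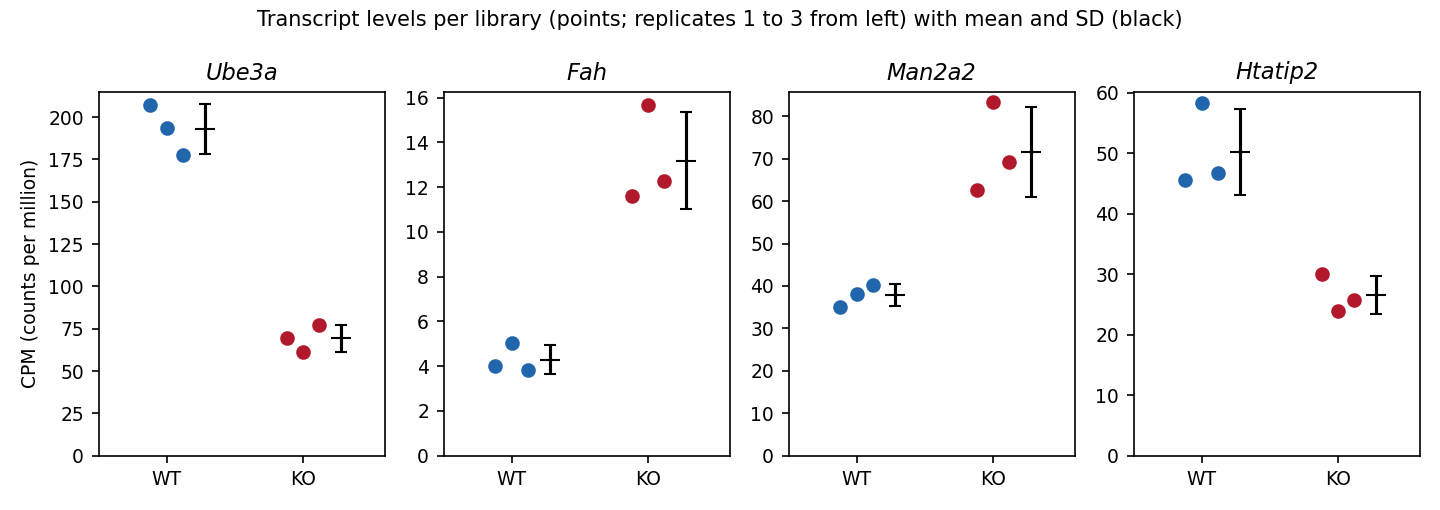
CPM (vertical axes, from 0) of Ube3a, Fah, Man2a2 and Htatip2 in the 3 WT and 3 KO libraries, with points for single libraries and black bars for the mean and SD. For Ube3a the KO libraries lie between 61.2 and 77.0 CPM and the WT libraries between 177.6 and 207.1 CPM; Man2a2 and Htatip2 did not pass the threshold.

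The genes with the next smallest p-values did not pass the threshold, and most of them also lay on chromosome 7. Man2a2, a Golgi mannosidase of N-glycan processing, stood at 71.7 ± 10.6 CPM in KO and 37.8 ± 2.596 in WT (log2 fold change 0.90; limma adjusted p = 0.146). Slco3a1, an organic anion transporter, stood at 21.3 ± 0.581 against 14.3 ± 0.0885 CPM (0.54; limma adjusted p = 0.182), and Hddc3, a hydrolase, at 8.21 ± 2.22 against 3.28 ± 0.118 CPM (1.08; limma adjusted p = 0.467). Hddc3 and Man2a2 share 1451 bp on opposite strands, and the use of strand in counting is not given in the sources used here, so reads in the shared part cannot be assigned. Ngrn, a factor of mitochondrial ribosome assembly, had a log2 fold change of 0.41, and Gm5452, a predicted gene on chromosome 13, one of 0.82. On the lower side, Htatip2 stood at 26.6 ± 3.17 against 50.2 ± 7.10 CPM (−0.89; limma adjusted p = 0.182). Cyfip1, a member of the WAVE actin-regulating complex, stood at 512.2 ± 12.04 against 660.9 ± 3.45 CPM (−0.37; limma adjusted p = 0.543). Oaf on chromosome 9 had a log2 fold change of −0.57, and Rmi2, part of the BLM helicase complex, and ENSMUSG00000116912, both on chromosome 16, had values of −0.56 and −0.79. Of the 9 genes with an unadjusted limma p under 0.001, 8 lay on chromosome 7.

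Both changed genes lay on chromosome 7, to which 926 of the tested genes belong. A two-sided Fisher's exact test gave p = 0.00585, but it counted the targeted gene, which lies there by design. Apart from Ube3a only Fah was counted, and 1 gene cannot show that changes gather on a chromosome. Within 10 Mb of Ube3a there were 40 tested genes, and the targeted gene itself was the only changed gene among them. Of the other 39, 13 had an unadjusted limma p under 0.05, 1 higher and 12 lower in KO, a share of 33.3% against 3.94% on the other chromosomes. Without KO replicate 2 these shares were 21.6% and 2.05%, and without WT replicate 2 they were 26.3% and 10.6%. The chromosome 7 count includes the targeted gene itself and was 1 in the fits without KO replicate 1, 2 or 3 and without WT replicate 1 or 3, with Fisher p from 0.07634 to 0.07666. That 1 gene was Ube3a, so these p-values follow from its position and test nothing further. Without WT replicate 2 the count was 2 of 8 changed genes (Fisher's exact test, p = 0.121). In the list of the imprinted region and its neighbours, all 10 tested members had negative log2 fold changes, with a median of −0.27. Over all genes tested, 1 of the 10, Ube3a, fell. When adjusted over the list alone, 6 fell, namely Ube3a, Cyfip1, Fan1, Atp10a, Nipa1 and Mtmr10. Atp10a, a phospholipid flippase gene next to Ube3a, had a log2 fold change of −0.48 ± 0.16 (SE, n = 3 per genotype), and Fan1, a DNA repair nuclease, one of −0.43 ± 0.11. Herc2, another HECT ligase and a reported partner of UBE3A, had a log2 fold change of −0.0049 ± 0.05. Fan1, Atp10a, Nipa1, Mtmr10 and Herc2 are named as members of this count and were picked after their values were seen.

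**Figure D2:**
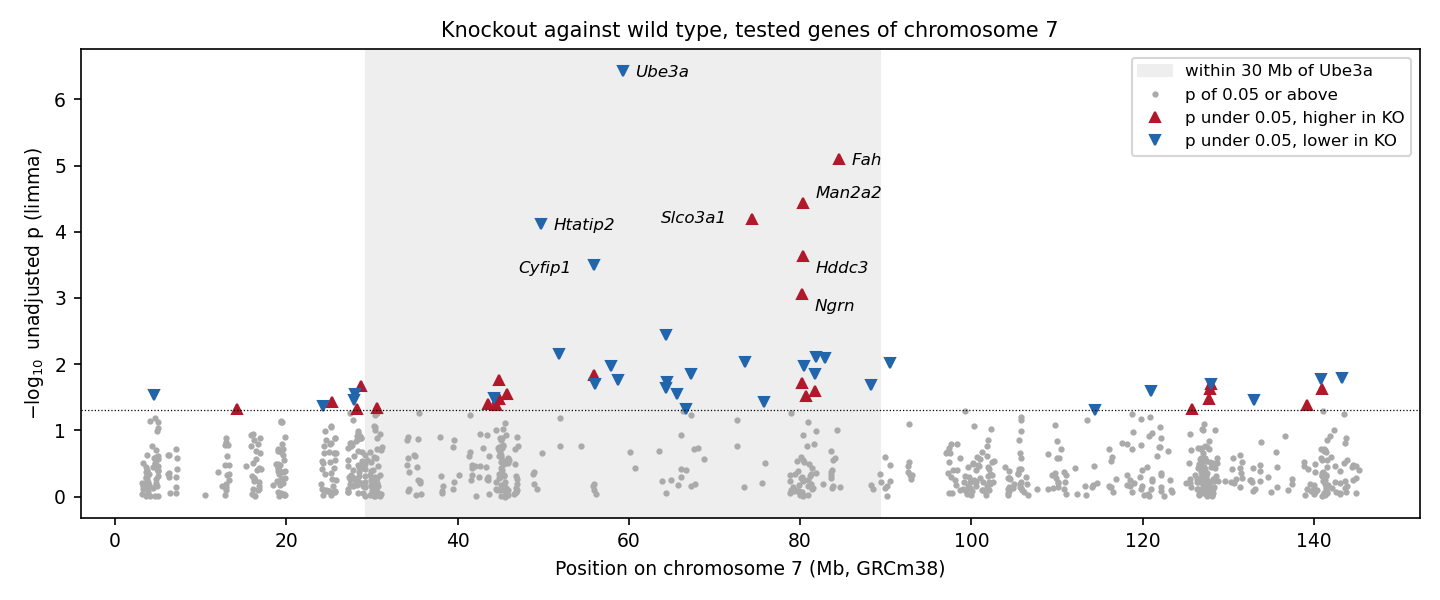
Each tested gene of chromosome 7 at its position (horizontal axis, Mb on GRCm38) with the negative log10 of its unadjusted limma p for KO against WT (vertical axis). Triangles mark p under 0.05, pointing up where higher and down where lower in KO; the grey band spans 30 Mb on either side of Ube3a and holds 37 such genes besides Ube3a among 281 tested.

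Snrpn, a paternally expressed gene of the same imprinted domain (chromosome 7: 59982495 to 60140219), lay far under the 1 CPM filter. It had 12, 11 and 10 reads in KO replicates 1 to 3 and 0 reads in every WT library. Against a floor of 3 reads over the WT group, its level in KO was at least 11.9-fold higher, a bound that allows for counting error in the WT reads but not in the KO reads, nor for differences between samples. With no filter on low values, limma gave an adjusted p of 0.507, and limma-voom over all genes gave an adjusted p of 0.107.

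Under the preset correlation of camera, genes that define macrophages and their lysosomes were slightly higher in KO as groups, and genes of DNA replication slightly lower, with no single member past the threshold. The core macrophage list rose (camera with the preset correlation, adjusted p = 0.0312), with 17 of 20 members positive and a median log2 fold change of 0.16. It did not pass with an estimated correlation (camera, p = 0.310, adjusted p = 0.9635). Its leading members were Fcgr1, the high-affinity IgG receptor, at 172.3 ± 17.0 against 121.8 ± 38.3 CPM, and Cd68, a lysosomal glycoprotein, at 1158 ± 89.7 against 987.9 ± 132.3 CPM. The list of lysosome and autophagy genes driven by TFEB rose (camera, adjusted p = 0.0312), with 16 of 22 positive and a median of 0.11, but not with an estimated correlation (p = 0.334, adjusted p = 0.9635). Gpnmb, a lysosomal membrane glycoprotein, stood at 1855 ± 284.8 against 1454 ± 353.3 CPM, and the protease Ctsd, which is in both lists, at 3224 ± 389.7 against 2618 ± 564.5 CPM. The S phase list fell (camera, adjusted p = 0.0390), with 17 of 22 members negative and a median of −0.06, but not with an estimated correlation (p = 0.187, adjusted p = 0.9635). Cyclin E2 (Ccne2) had a log2 fold change of −0.29 and the replication factor Cdc45 one of −0.14.

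With no filter on low values none of the 3 lists passed (camera adjusted p = 0.0628 for the core macrophage and lysosome lists and 0.0639 for the S phase list). The S phase list also missed the threshold with the replicate number as a block, with Xist as a covariate (camera adjusted p = 0.0601) and without both libraries that have almost no Xist (0.581). Which of these lists passed depended on the libraries included, although each of the 3 kept its direction in all 6 fits without 1 library. The core macrophage list had a camera adjusted p of 0.0813 without KO replicate 1, 0.130 without KO replicate 2, 0.287 without WT replicate 1 and 0.233 without WT replicate 3. The lysosome list had 0.327 without KO replicate 1, 0.444 without WT replicate 1 and 0.243 without WT replicate 3, and the S phase list had 0.183 without KO replicate 2, 0.135 without KO replicate 3, 0.297 without WT replicate 2 and 0.0999 without WT replicate 3 (camera adjusted p). The core macrophage list passed without KO replicate 3 (0.00485) and WT replicate 2 (4.65e-06), the lysosome list without KO replicate 2 (0.00408), KO replicate 3 (0.0339) and WT replicate 2 (2.02e-05), and the S phase list without KO replicate 1 (0.00977) and WT replicate 1 (0.0114). The genotypes overlapped by library: relative to the mean of all 6, the core macrophage list stood at 0.146, 0.15 and −0.0448 in KO replicates 1 to 3 and at −0.245, 0.173 and −0.18 in WT, with WT replicate 2 highest. The lysosome list stood at 0.141, 0.0104 and 0.0158 in KO and at −0.182, 0.137 and −0.122 in WT. The S phase list stood at 0.0274, −0.0868 and −0.0384 in KO and at 0.0105, 0.0715 and 0.0158 in WT. The neutrophil and the stem and progenitor lists went the other way from the core macrophage and lysosome lists in the WT libraries, at 0.394 and 0.278 in WT replicate 1, −0.36 and −0.229 in WT replicate 2, and 0.355 and 0.301 in WT replicate 3. In KO replicates 1 to 3 the neutrophil list stood at −0.556, 0.0224 and 0.144, and the stem and progenitor list at −0.231, −0.0698 and −0.0506.

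**Figure D3:**
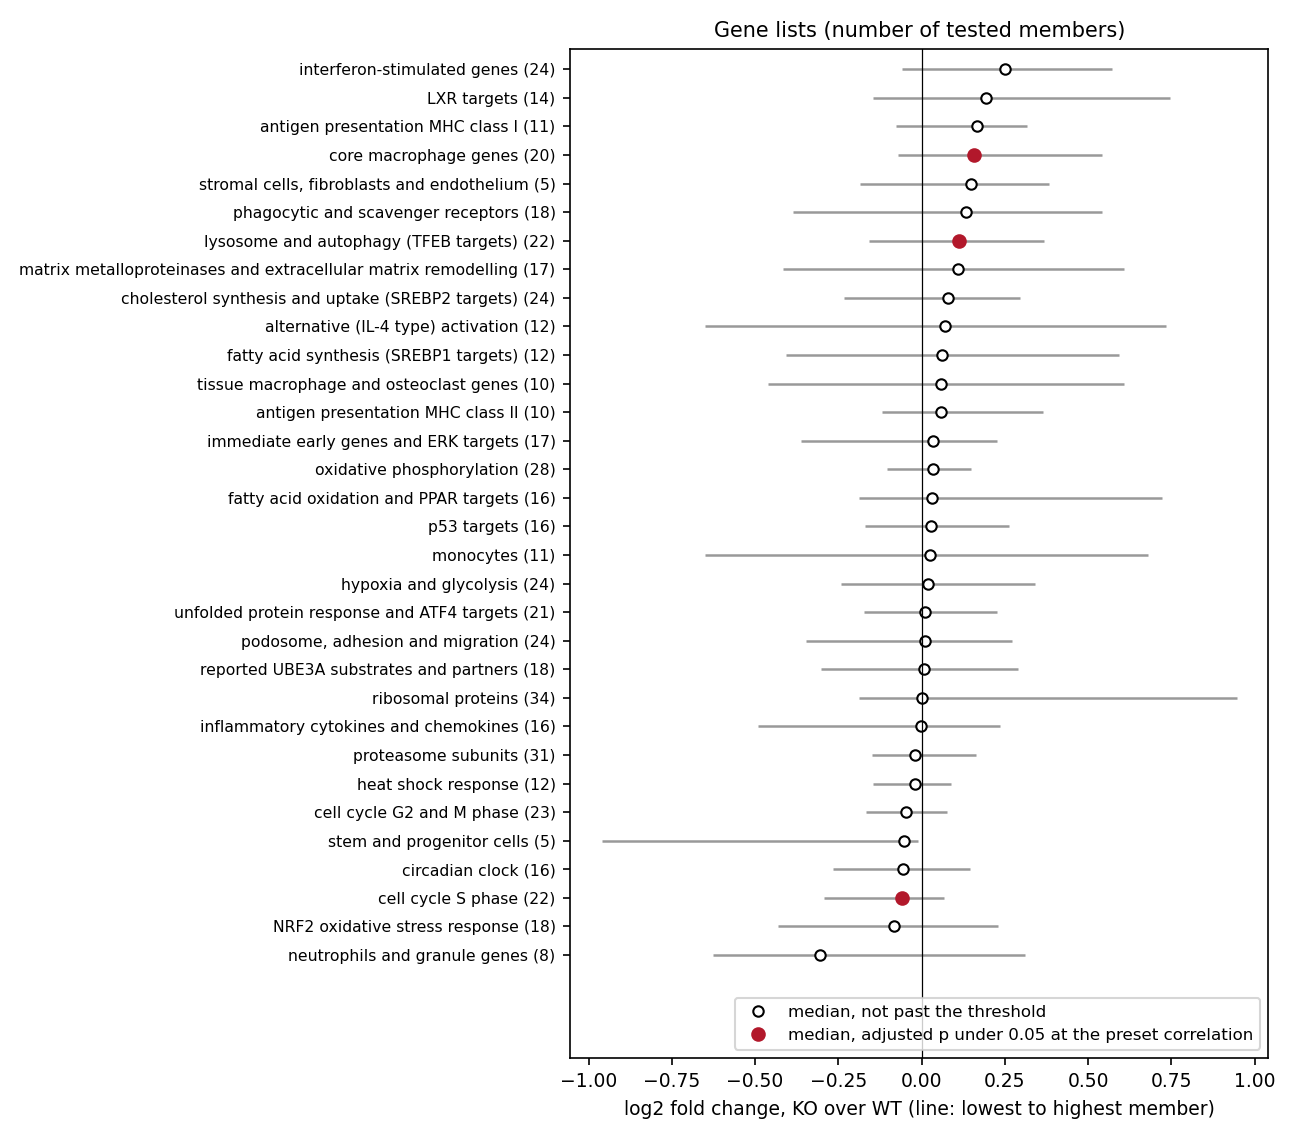
Median log2 fold change, KO over WT (circle), and the lowest to highest member (line) of each of the 32 lists with at least 5 tested genes. Filled circles mark the core macrophage, lysosome and S phase lists, whose camera adjusted p was under 0.05 with the preset correlation and 0.9635 with an estimated one.

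Lipid-handling genes passed no list test. Targets of LXR, the sterol-sensing receptor that drives cholesterol efflux, had a median log2 fold change of 0.19, with 12 of 14 positive (camera adjusted p = 0.214). Abca1, the cholesterol efflux pump, stood at 242.1 ± 16.7 CPM in KO and 212.7 ± 97.6 in WT, a log2 fold change of 0.29 with a 95% interval of −0.37 to 0.95. Abcg1 had 0.16 (−0.41 to 0.72), Mertk 0.22 and Tmem86a 0.30. SREBP2 targets of cholesterol synthesis and uptake had a median of 0.08 over 24 genes (camera adjusted p = 0.314), with Mvd at 0.30 and Dhcr7 at 0.19. SREBP1 targets of fatty acid synthesis had a median of 0.06 over 12 genes (camera adjusted p = 0.667), with Me1 at −0.41 and Fads1 at 0.12. Fatty acid oxidation and PPAR targets had a median of 0.03 over 16 genes (camera adjusted p = 0.603), with the fatty acid binding protein Fabp5 at 0.72 (−0.04 to 1.49) and the lipid droplet coat Plin2 at 0.17.

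Inflammatory and antigen presentation genes passed no list test either. Cytokines and chemokines had a median log2 fold change of −0.0026 over 16 genes (camera adjusted p = 0.945), with Cxcl10 at −0.36 and Cxcl2 at −0.34. Tnf stood at 54.0 ± 3.53 CPM in KO and 58.2 ± 8.32 in WT (−0.10; 95% interval −0.35 to 0.15), and Il1b, at 0.175 and 0.347 CPM, was under the filter. Interferon-stimulated genes were positive in 22 of 24 members, with a median of 0.25 (camera adjusted p = 0.278), and included Stat2 at 0.25 and Gbp2 at 0.27. The level of this list differed far more between libraries of one genotype than between genotypes. Relative to the mean of all 6 libraries it was 0.95, −0.78 and 0.16 on the log2 scale in KO replicates 1 to 3, and −0.72, 0.80 and −0.41 in WT replicates 1 to 3. MHC class I genes had a median of 0.17 over 11 genes (camera adjusted p = 0.278), with H2-K1 at 0.32 and H2-D1 at 0.28, and MHC class II genes a median of 0.06 over 10 (camera adjusted p = 0.608), with H2-Eb1 at 0.36 and H2-Ab1 at 0.16. Reads of H2 genes can be shared between near-identical family members, so these values are uncertain.

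**Figure D4:**
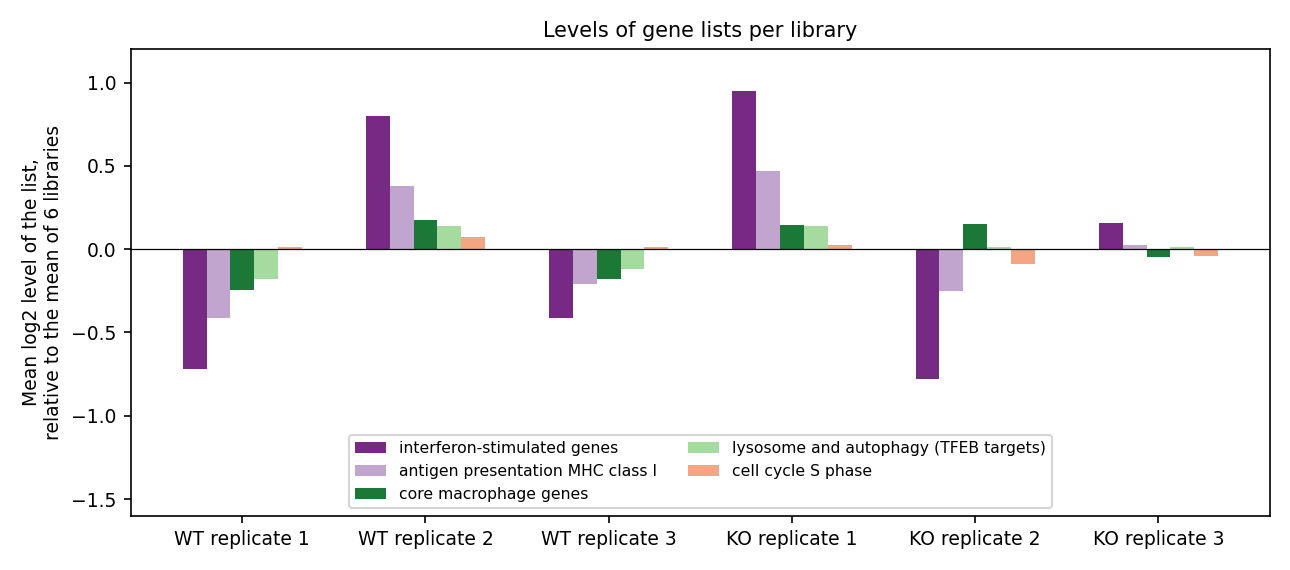
Mean log2 level of 5 gene lists in each library, relative to the mean of the 6 libraries (bars, from 0). The interferon-stimulated list reaches 0.95 in KO replicate 1 and 0.80 in WT replicate 2, and is lowest in KO replicate 2 at −0.78 and WT replicate 1 at −0.72.

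Genes of alternative, IL-4 type activation had a median of 0.07 over 12 genes (camera adjusted p = 0.305), with the mannose receptor Mrc1 at 742.7 ± 189.6 against 473.0 ± 238.2 CPM and Clec10a at a log2 fold change of 0.35. Phagocytic and scavenger receptors had a median of 0.13 over 18 genes (camera adjusted p = 0.278), with the Fc receptor Fcgr4 at 0.45. Matrix metalloproteinases and matrix remodelling genes had a median of 0.11 over 17 genes (camera adjusted p = 0.608), with the inhibitors Timp1 at 0.44 and Timp2 at 0.42. Mmp9, the gelatinase, was not resolved, at 20.5 ± 8.75 CPM in KO and 19.9 ± 23.5 in WT with a 95% interval of −1.09 to 2.30. Podosome, adhesion and migration genes had a median of 0.01 over 24 genes (camera adjusted p = 0.965), with the integrins Itgav at −0.27 and Itgb3 at 0.27.

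Genes tied to the ubiquitin system passed no list test. Reported UBE3A substrates and partners had a median of 0.01 over 18 genes (camera adjusted p = 0.965), with Sod2 at −0.15 and Rad23b at −0.14. Proteasome subunits had a median of −0.02 over 31 genes (camera adjusted p = 0.608), with Psmd14 at −0.15 and Psmc6 at −0.10. The other HECT-type ligases had a median of −0.01 over 23 genes, none of which passed, with Hectd2 at −0.41 and Hace1 at −0.17.

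The other lists of growth, stress and energy genes did not pass. G2 and M phase genes had a median of −0.05 over 23 genes (camera adjusted p = 0.278), with Bub1 at −0.17 and Ccna2 at −0.15, and p53 targets one of 0.03 over 16 (camera adjusted p = 0.945), with Aen at 0.22 and Trp53inp1 at −0.17. NRF2 targets had a median of −0.08 over 18 genes (camera adjusted p = 0.278), with Gclc, which limits glutathione synthesis, at −0.30. The median was 0.02 for hypoxia and glycolysis over 24 genes (camera adjusted p = 0.793), with Ndrg1 at 0.34 and Gapdh at −0.24, a gene whose reads can be lost to its many pseudogenes. It was 0.03 for oxidative phosphorylation over 28 (camera adjusted p = 0.278), with Sdhc at 0.14 and Ndufa2 at 0.13, and 0.01 for the unfolded protein response over 21 (camera adjusted p = 0.793), with Atf3 at 0.23 and Sesn2 at 0.18. Heat shock genes had a median of −0.02 over 12 (camera adjusted p = 0.943), with Hsph1 at −0.15 and Hspd1 at −0.11. Immediate early genes had one of 0.03 over 17 (camera adjusted p = 0.945), with Jun at 0.16. Clock genes had a median of −0.06 over 16 (camera adjusted p = 0.504), with Nr1d2 at −0.27 and Nfil3 at 0.14, and ribosomal protein genes, whose reads are shared with pseudogenes, had a median of 0.00 over 34 (camera adjusted p = 0.946), with Rpl30 at −0.19.

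Several lists of other cell types had few members above the filter, and no tested list of them passed. Some of their members were well expressed: mean CPM in KO and WT was 165.5 and 146.8 for Irf8, 127.2 and 146.8 for Il7r, and 85.2 and 74.4 for Pf4. Monocyte markers had a median of 0.02 over 11 genes (camera adjusted p = 0.946), with F13a1 at 162.2 ± 85.0 against 91.3 ± 5.73 CPM and Treml4 at a log2 fold change of −0.60, and tissue macrophage and osteoclast genes one of 0.06 over 10 (camera adjusted p = 0.865), with Dcstamp at −0.46 and Tnfrsf11a at −0.13. Neutrophil and granule genes had a median of −0.31 over 8 of their 20 members (camera adjusted p = 0.278), with S100a9 at 2.23 ± 0.912 against 3.91 ± 1.498 CPM and Lcn2 at a log2 fold change of −0.33. Stem and progenitor genes were negative in 5 of 5, with a median of −0.05 (camera adjusted p = 0.278), led by Cd34 at 28.1 ± 5.15 against 60.1 ± 27.0 CPM (−0.96; 95% interval −1.75 to −0.17) and with Tal1 at −0.12. Stromal, fibroblast and endothelial genes had a median of 0.15 over 5 (camera adjusted p = 0.824), with Vwf at 0.38 and Acta2 at −0.19. The lists for dendritic cells (Irf8 at 0.17, Cd83 at 0.15), B cells (Blnk at 0.30, Ighm at 0.24) and adipocytes (Lipe at 0.23, Fabp4 at 0.09) had 3 tested genes each, with medians of 0.15, 0.24 and 0.09. T and NK cells (Il7r at −0.25) and erythroid and megakaryocyte cells (Pf4 at 0.17) had 1 tested gene each, and mast cells, basophils and eosinophils had 0.

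Of the sex-linked genes, Xist was the only one tested. Xist, which is transcribed from the inactive X chromosome of female cells, was nearly absent from 1 library of each genotype, with 28 reads in KO replicate 2 and 14 in WT replicate 2 against 30161 to 42232 reads in each of the other libraries. With Xist as a covariate, Ube3a and Fah were again the 2 genes past the limma threshold. When both libraries with almost no Xist were left out, 23 genes and 13 lists passed, and without WT replicate 2 alone 8 genes and 10 lists passed (limma and camera with Benjamini-Hochberg adjustment). Without both, KO replicates 1 and 3, where the interferon-stimulated list stood at 0.95 and 0.16, are set against WT replicates 1 and 3, where it stood at −0.72 and −0.41. Leaving out WT replicate 2 brought past the threshold the lists of interferon-stimulated genes (camera adjusted p = 9.11e-05), MHC class I (0.00155), LXR targets (9.61e-05), G2 and M phase (9.61e-05), NRF2 targets (0.00235), stem and progenitor genes (0.00374), neutrophil genes (0.0250) and, with its direction turned to lower, monocyte markers (0.0159). Leaving out KO replicate 2 did so for interferon-stimulated genes (camera adjusted p = 6.17e-07) and MHC class I (0.00441), leaving out KO replicate 3 for G2 and M phase (0.0292), and leaving out KO replicate 1 or WT replicate 3 for SREBP2 targets (1.57e-06 and 0.0195). Other fits turned some of these lists around. The lists of LXR targets, NRF2 targets, stem and progenitor genes and neutrophil genes kept their direction in every fit without 1 library. Among those fits they passed only without WT replicate 2. Interferon-stimulated and MHC class I genes were lower without KO replicate 1 (camera adjusted p = 0.389 and 0.856) and without WT replicate 1 (0.713 and 0.871). G2 and M phase genes were higher without KO replicate 1 (0.924) and WT replicate 3 (0.991). SREBP2 targets were lower without KO replicate 2 (0.808), KO replicate 3 (0.935) and WT replicate 1 (0.864). All these list tests used the preset correlation, and an estimated one was not run with libraries left out. With all libraries, estimating it moved the unadjusted camera p from 0.0884 to 0.717 for interferon-stimulated genes and from 0.104 to 0.625 for MHC class I.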

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

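The fits on the deposited log2 CPM, with limma-voom on all genes, without both libraries that have almost no Xist and with unscaled totals were chosen after seeing the data. Ube3a passed the limma threshold in each of its 19 alternatives, with log2 fold changes from −1.54 to −1.38 and adjusted p from 0.00200 to 0.0436. No scaling moved the median log2 fold change by more than 0.1: other size factors moved it by −0.000117 and 0.00620 and unscaled totals by −0.00740, and under these 3 scalings the 2 genes and 3 lists kept their calls. The count of changed genes and that on chromosome 7 were both 1 with no filter on low values, with the stricter filter, with a pseudocount of 5 and with limma-voom on recovered reads, because Fah then just missed the threshold (limma adjusted p from 0.0535 to 0.0756, over a full range of 0.00547 to 0.407); the log2 fold change of Fah was 1.42 with no filter and with the stricter one, 0.96 with a pseudocount of 5 and 1.63 with limma-voom. With no filter 0 lists passed, the smallest camera adjusted p being 0.0628, and the cause was not tested. With an estimated correlation 0 lists passed (camera, smallest adjusted p 0.9635) and with fry 0 (0.9638), with 0 of 32 at an unadjusted p under 0.05 in each. Without both libraries that have almost no Xist, 23 genes and 13 lists passed, 4 of the genes on chromosome 7 and 2 within 10 Mb of Ube3a; Xist was then at −0.12 and Il7r at 0.18, and the cause was not tested. Leaving out 1 library gave 1 to 8 changed genes, 1 to 2 of them on chromosome 7, and 1 to 10 lists, with both highest gene and list counts without WT replicate 2; fewer samples also lower the power. The cause of these reversals with 1 library left out was not tested: Pf4 ranged from −0.000625 to 0.29, Il7r from −0.45 to 0.0425, Abca1 from −0.0540 to 0.63, Mmp9 from −0.11 to 1.53, Cd83 from −0.0199 to 0.33, Abcg1 from −0.12 to 0.44, Fabp4 from −0.0649 to 0.24 and Xist from −3.20 to 3.11. Xist was also at −0.0480 with a pseudocount of 5, and none of these genes passed the threshold. Of 1110 fold changes of the reported named genes under the other settings, 1099 kept their direction and side of the threshold, and of 516 with 1 library left out 500 did. With the replicate block, 2 genes and 2 lists passed (limma and camera); Ube3a and Fah had an adjusted p of 0.0318 each, and the S phase list had 0.0588. Replicate numbers do not pair the libraries: same-numbered libraries correlated at −0.22, −0.13 and 0.14 in their deviations from the group means, and each KO library correlated best with a WT library of another number. The planned DESeq2 test was not run, since the deposited columns are not counts, although the recovered reads would have allowed it. Whether Fah would pass with such a test is therefore not known. The planned size-factor, filter and voom alternatives were run with limma. Depth limits the low genes: a gene with 0 reads in a library may stand at up to 0.0832 to 0.120 CPM there, taking 3 reads as the limit.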

Other observations

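The tests of distance from Ube3a, of Xist, of other cell types, of genotype and of single cultures in this part, the repeated thinnings, the counts of other splits, and the genes of the first paragraph were chosen only after the result was seen. The windows of 5, 10 and 20 Mb and the tests at equal depth in a single thinning were set down before.

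Beside Snrpn, 2 more low genes close to Ube3a differed in reads. Ndn, a paternally expressed gene of the imprinted domain (chromosome 7: 62346569 to 62350262), had 7, 22 and 20 reads in KO replicates 1 to 3 and 1, 0 and 1 in WT, a ratio of 26.4 with a 95% counting interval of 6.94 to 224. Gm44829 (chromosome 7: 59318631 to 59321823), a predicted gene on the strand of Ube3a just past its end, had 2, 2 and 5 reads in KO and 22, 18 and 15 in WT, a ratio of 0.177 (0.0767 to 0.3602). Neither passed with limma and no filter (adjusted p = 0.896 for Ndn and 0.762 for Gm44829), nor with limma-voom over all genes (0.658 and 0.879). The intervals of both ratios come from reads pooled within each genotype, and do not allow for differences between samples.

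Between the libraries, the first principal component held 43.2% of the variance and did not follow genotype. It ran from −16.9 in WT replicate 2 and −13.4 in KO replicate 1, through 0.47 and 0.51 in KO replicates 2 and 3, to 12.01 in WT replicate 3 and 17.3 in WT replicate 1. Irf7, a master regulator of interferon genes, stood at 352 CPM in KO replicate 1 and 239 in WT replicate 2, against 28.9 to 99.9 in the rest, and Ifit3 at 30.2 and 25.2 against 3.59 to 11.2. Irf7 and Ifit3 were picked after their values were seen.

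Genes with a small p-value gathered around Ube3a: 33.33% of the 39 other genes within 10 Mb and 13.17% of the 281 within 30 Mb had p under 0.05 (limma), against 3.94% on the other chromosomes. The 30 Mb share was 7.53% without KO replicate 2 and 7.55% without WT replicate 1, against 2.05% and 1.08% on the other chromosomes. Without WT replicate 2 it was 15.7% against 10.6%. A response without regard to position is argued against by the 10 Mb window (Fisher p = 1.988e-09, although genes are not independent), and an effect on the immediate neighbours alone by the genes 5 to 20 Mb away, of which 13.87% had p under 0.05, 8 higher and 11 lower (Fisher p = 2.58e-06). Without KO replicate 1, KO replicate 2 or WT replicate 1 this last share was 8.82%, 6.62% or 6.67%, against 4.12%, 2.05% or 1.08% on the other chromosomes, and without WT replicate 2 it was 15.4% against 10.6% (Fisher p = 0.0917). A candidate explanation is sequence of another strain kept around the targeted gene, but the strains are not given in the labels, and an added effect of the deletion stays open, since up to 5 Mb away 35.7% of 14 genes had p under 0.05, 1 higher and 4 lower. Of the 10 splits of the 6 libraries, 1, the real one, gave so large a share within 30 Mb; the highest other was 9.25%, in a split with 1928 genes at p under 0.05 in all against 500 in the real one, and 10 splits are too few for a share under 0.05.

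The interferon-stimulated list varied by 1.73 on the log2 scale between libraries, and by 1.727 within the KO libraries, which is the pattern itself, so a part played by genotype stays open. Sex as the whole cause is argued against by the libraries with almost no Xist, KO replicate 2 and WT replicate 2, which lay 1.579 apart. Counting noise from unequal depth is argued against by thinning all libraries to the depth of the smallest, 25454862 reads, which left a range of 1.719. Thinning keeps the expected CPM of each gene, so it cannot test other differences that go with depth. KO replicate 1 and WT replicate 2, highest in the list, also had the fewest reads, 25454862 and 28651459, against 30957583 to 35517269 in the rest. Other cell types are not excluded: the core macrophage list varied by only 0.4181, but its high baseline would hide a small share of other cells, and KO replicate 1 and WT replicate 2, against WT replicates 1 and 3, had neutrophil lists at −0.556 and −0.36 against 0.394 and 0.355, monocyte lists at −0.194 and −0.398 against 0.195 and 0.173, and dendritic cell lists of 3 genes at 0.279 and 0.521 against −0.413 and −0.275, although KO replicate 2, lowest in the interferon list at −0.777, stood near the mean in these 3, at 0.0224, 0.0482 and 0.0105. Cell mix, maturity or exposure to interferon may differ between cultures or animals, which the labels do not describe.

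The higher core macrophage and lysosome lists and the lower S phase list could reflect differences between single cultures, since 0 of the 6 fits without 1 library kept all 3 calls (camera), although each list kept its direction in all 6 and fewer samples also lower the power. At equal depth the medians stayed nearly as large, at 0.157 from 0.159 for the core macrophage list, 0.103 from 0.112 for the lysosome list and −0.0559 from −0.0590 for the S phase list, with spreads between members of 0.160, 0.133 and 0.0816. Counting noise from unequal depth as the whole cause is argued against for the core macrophage list, which passed in 20 of 20 thinnings (camera, highest adjusted p = 0.03784). The lysosome list passed in 18 and the S phase list in 15. In the first thinning both had a camera adjusted p of 0.05407, against 0.0312 and 0.0390 with all reads. Single cultures and loss of Ube3a cannot be told apart for the 3 lists with 3 libraries per genotype. Counting noise from depth is not excluded for the lysosome and S phase lists, and other differences that go with depth are not excluded for any of the 3. Of the 10 splits, 7, the real one among them, gave 3 lists or more, with 14 the highest of the others. The count of 3 lists thus did not set the split by genotype apart from other splits of the libraries. With 10 splits no share under 0.05 could have been reached.

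For the changed genes, 2 of the 10 splits gave 2 genes or more, the real one and that of KO replicates 1 and 3 with WT replicate 2 against the rest, which called 43, or 21.5 times as many, 13 of them in the interferon and MHC class I lists. Such a split points to a structure of the samples other than genotype. For calls on chromosome 7, 2 of the 10 splits gave 2 genes, which was also the highest of the others. In the real split these were 2 of 2 calls, with the targeted gene among them, and in the other split 2 of 43. With 10 splits no share under 0.05 can be reached.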
